A study of Mus musculus with 3 samples.

How the data were processed

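The samples were cell suspensions from quadriceps muscle of wildtype C57BL/6 mice, a common inbred laboratory strain. Per the labels, muscle tissue had been surgically removed (volumetric muscle loss) and the defect filled with particles of polycaprolactone (PCL), a synthetic degradable polyester, and the tissue was taken at week 6. Per the labels' protocols, dead cells were removed by magnetic sorting, cells were separated magnetically into fractions with and without CD45, the surface protein of leukocytes, and the fractions were remixed 1:1. Droplet libraries were made with 10x Genomics 3′ chemistry, version 3.1, and sequenced on a NovaSeq to a target of 100000 reads per cell. This remix, and not the tissue, can set the share of immune against stromal cells. The labels give 1 group of 3 libraries, named here replicate 1, replicate 2 and replicate 3, with no untreated or sham group, so every comparison was made between classes of cells within libraries. The labels do not say that the replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical.

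The deposited matrices hold UMI counts (unique molecular identifiers, 1 per captured molecule) per gene and barcode, whole numbers with no normalization. Per the file headers, the software that wrote the counts was version 7.0.0, while the submitters' processing notes name Cell Ranger 6.1.2, and this difference could not be settled here. The genome build, the annotation and whether intronic reads were counted are not given in the sources used here, so no coordinates are printed. Each matrix has 32285 genes, of which 32158 identifiers were found in the reference table of gene names; symbols are those of the files. The matrices hold called cells only, with no barcode under 500 UMIs, so empty droplets could not be used to estimate free RNA. Replicates 1, 2 and 3 held 6068, 8643 and 4996 barcodes, 136519688, 192348779 and 104482261 UMIs, and medians of 17855.5, 20286 and 17008.5 UMIs and 4279.5, 4561 and 4180.5 genes per barcode. The libraries were checked for duplicates. The chi-square statistic per gene between pairs lay between 65.8 and 331.4, far above sampling noise, so each library counted as 1 replicate.

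Cells were kept with at least 500 UMIs, at least 200 genes and a mitochondrial share of at most 20%. Doublets were scored with Scrublet as run in scanpy 1.11.5, and the top-scoring barcodes were removed at 0.8% per 1000 barcodes, which were 295, 598 and 200 barcodes (4.86%, 6.92% and 4.00%). Scrublet's automatic threshold would have marked 71, 157 and 25 (1.17%, 1.82% and 0.500%). Of the barcodes, 5652, 7692 and 4604 were kept, 17948 in all. Counts were scaled to 10000 per cell, log-transformed, and 2000 variable genes chosen with no gene of the fixed lists among them. Leiden clusters (resolution 1.0, 30 principal components, 15 neighbors, leidenalg 0.10.2, igraph 0.11.9) were built in Python 3.11.15 with anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0. There were 33 clusters. Clusters with mixed markers, with T and NK markers or without a name were split again on 15 components at the same resolution, giving 75.

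Each cluster was named from 32 fixed marker lists by a score, the mean level of a list's genes relative to their highest cluster times the share of the list detected in at least 25% of the cluster's cells. A name needed at least 3 detected markers, a score of at least 0.15 and at least 1.5 times the next class. A cluster also stayed unnamed when its top 10 genes held more markers of another class, or when its cells had under 1/3 of their library's median UMIs and none of its markers among those genes. The markers were fixed beforehand, and the thresholds of the score were chosen after marker tables had been seen. By these thresholds 15 clusters with 677 cells stayed unnamed and entered no comparison. They made up 3.91% ± 0.841 of the cells (mean ± SD, n = 3). All classes are called "-like", since no annotation by the authors was used.

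For each comparison UMIs were summed per library and side and tested with edgeR 4.0.16 (R 4.3.3, limma 3.58.1) by the quasi-likelihood test, with filterByExpr, TMM scaling and the library as a block, since both sums of a library come from the same suspension. The SE is the log2 difference over the root of F and was left blank where F was near 0. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 difference of at least 1, and a side needed at least 20 cells in every library. Comparisons were immune-like against stromal-like cells, macrophage-like against other immune-like cells, T- and NK-like (with innate lymphoid) against other immune-like cells, fibroblast-like against other stromal-like cells, and endothelial-like (with lymphatic) against other stromal-like cells. Levels are CPM (counts scaled to the same total in every sum) computed from the authors' deposited counts with TMM library sizes, as mean ± SD over 3 libraries. Macrophage-like and fibroblast-like cells were clustered again at resolution 0.5, and each subcluster with at least 20 cells in every library was tested against the mean of the logs of the others, in genes of the fixed lists only.

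There were 21 gene lists with 309 genes, of which 308 were measured and Mx1 was missing. They cover interstitial matrix, basement membrane, matrix proteases and inhibitors, macrophage fusion, lipid handling, pro-inflammatory mediators, other chemokines, type 2 macrophage genes, IL-17 producing lymphocytes, IL-17 response, T cell effectors, antigen presentation, senescence, hypoxia and angiogenesis, complement, interferon response, growth factors of fibrosis, contractile genes, neural genes, cell cycle and dissociation stress. Each list was tested against the other genes with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, and with fry, adjusted over the lists. The estimated correlation rests on the 2 residual degrees of freedom of each comparison. That form therefore has little power, and a list it leaves uncalled may still differ. Fry asks whether a list's genes move, on balance, 1 way, or in its mixed form whether they change in either direction, and neither form compares the list with other genes.

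Named genes followed a rule. From each list with at least 3 called members it takes the largest rise and the largest fall, given the same direction in all 3 libraries and at least 20 CPM on the higher side. It adds the 5 largest rises and falls among genes in no list, in no marker list and not used for clustering. Ptprc, Pdgfra, Col1a1, Spp1, Trem2, Cd9, Cdkn1a, Cdkn2a, Il17a and Il17ra were named wherever measured, and for subclusters up to 3 list genes with the largest rise. The text prints those of them that describe a list, and some are not reported here. Genes named outside the rule, chosen after their values were seen, are listed without statistics or given as levels. The comparisons, tests, lists, markers, the rule for named genes and 16 alternative settings were fixed before the data were examined, and 3 settings that leave out doubted cells were added afterwards. Genes with near-identical copies, such as Ccl3 and Ccl4, Hspa1a and Hspa1b, Saa3, the Klrc and Sirpb1 families, H2 genes and immunoglobulin genes, are uncertain where shared reads were split or dropped. The strand setting of the counting was not recorded either, so overlapping genes are uncertain.

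The fits were tested on simulated counts with 200 changed genes per comparison. All other genes had the same mean on both sides, no library effect was drawn, and the spread followed its trend with level. The real comparisons differ from this, with 8691 of 17630 genes called between immune-like and stromal-like cells. The rates that follow hold for the simulated setting and may not hold for the real sums. At 3-fold changes 86.4% were recovered for immune-like against stromal-like, 94.4% for macrophage-like, 65.8% for T- and NK-like, 85.5% for fibroblast-like and 80.9% for endothelial-like sums, and at 8-fold changes 97.9%, 96.7%, 83.1%, 93.2% and 95.3%. Exact binomial (Clopper-Pearson) intervals at 95% and floors of 3 counts cover counting error only. DESeq2 1.42.0 was an alternative test, and figures were drawn with matplotlib 3.10.9.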

Results

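Single-cell RNA sequencing was used to profile the immune and stromal cells around a synthetic implant in injured muscle. The quadriceps of C57BL/6 mice had been given a volumetric muscle loss, a defect too large for muscle to regenerate fully, and filled with particles of polycaprolactone, a polyester that provokes a foreign body response. The tissue was taken at week 6. There were 3 libraries of 1 group, with 6068, 8643 and 4996 barcodes and 136519688, 192348779 and 104482261 UMIs for replicates 1, 2 and 3. After filtering, 17948 cells remained, and the comparisons were made between classes of cells within these libraries. Levels are CPM, counts scaled to the same total in every sum, as mean ± SD over the 3 libraries, and log2 differences are given with their standard error (SE).

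Fibroblast-like and macrophage-like cells made up most of the filtered cells. Fibroblast-like cells, the matrix-producing cells of connective tissue, were 52.0% ± 15.8 (SD, n = 3) and macrophage-like cells, tissue phagocytes, 19.9% ± 10.4. Neutrophil-like cells were 5.19% ± 2.85, endothelial-like cells of blood vessels 4.97% ± 1.15, monocyte-like cells 3.86% ± 1.66, and the pericytes and smooth muscle of vessel walls, named mural-like, 1.77% ± 0.187. Few of the filtered cells were muscle, with 1.47% ± 0.740 muscle fibre-like and 0.306% ± 0.246 satellite- or myoblast-like cells, the progenitors of muscle (0.584%, 0.117% and 0.217% in replicates 1, 2 and 3). These shares of captured cells do not measure how much muscle the tissue held. The muscle fibre-like share was 0.517% with at least 1000 genes per cell, and no such cells were left without the clusters of very low UMIs. T- and NK-like lymphocytes were 0.784% ± 0.242, without the unnamed clusters 18.2, 18.3 and 18.8 (52, 47 and 26 cells), whose best score was for T or NK cells. The magnetic separation and 1:1 remix of CD45 fractions bear directly on the totals of 32.4% ± 13.5 immune-like and 63.7% ± 14.3 stromal-like cells. Within the immune-like cells macrophage-like cells were 59.2% ± 11.9, neutrophil-like cells 17.1% ± 7.45 and monocyte-like cells 12.3% ± 2.59. Within the stromal-like cells fibroblast-like cells were 80.8% ± 6.58 and endothelial-like cells 8.27% ± 3.30. The fibroblast-like share differed between replicates 1, 2 and 3 (40.1%, 70.0% and 46.0%), as did the macrophage-like share (23.7%, 8.20% and 27.9%). Median depth also differed between classes, from 26439 UMIs in fibroblast-like and 11959 in macrophage-like cells to 5137 in neutrophil-like and 1588 in muscle fibre-like cells.

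**Figure D1:**
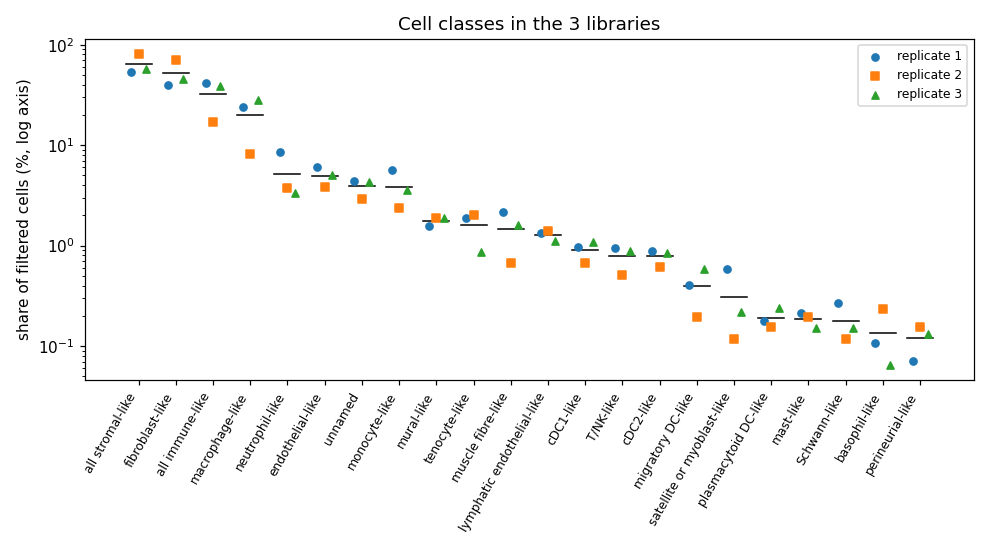
Share of filtered cells in each cell class, in percent on a log axis, with 1 marker per replicate and a line at the mean. Fibroblast-like cells have the highest share in each library, and macrophage-like cells vary between 8.20% and 27.9%.

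Immune-like cells were compared with stromal-like cells to ask which transcripts each compartment carried. Most genes of the lists for inflammatory cytokines, antigen presentation and lipid handling were higher in immune-like cells, and most for interstitial matrix, basement membrane and fibrosis growth factors in stromal-like cells. Camera called these lists at the preset correlation, and no list with an estimated correlation (smallest adjusted p = 0.355). With 2 residual degrees of freedom in each comparison, the estimated form can miss lists that differ, here and below. Cd86, a costimulatory ligand for T cells, was at 254.4 ± 18.6 CPM in immune-like against 0.475 ± 0.195 CPM in stromal-like cells (log2 difference 9.15, SE 0.25). Il1b, which encodes the cytokine IL-1β, was at 1009 ± 219.1 against 3.30 ± 2.42 CPM (log2 8.45, SE 0.37, the latter level being 1.90 CPM without replicate 1). Col1a1, a chain of type I collagen, was at 188.6 ± 112.5 against 11430 ± 1096 CPM (log2 −6.08, SE 0.34), the immune-like level falling to 123.9 CPM without replicate 2, and Il33, an alarmin cytokine of barrier and stromal cells, at 3.30 ± 1.45 against 246.2 ± 41.7 CPM (log2 −6.29, SE 0.16). The edgeR quasi-likelihood test gave Benjamini-Hochberg adjusted p = 1.7e-06 for Cd86, 7.12e-06 for Il1b, 1.74e-05 for Col1a1 and 1.52e-06 for Il33, each in the same direction in 3 of 3 libraries.

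Of 17630 genes tested between immune-like and stromal-like cells, 3487 were higher and 5204 lower in immune-like cells. Of the 15742 genes that were neither markers nor used for clustering, 2691 were higher and 4392 lower. Of 25 interstitial matrix genes, 23 were lower in immune-like cells, among them Tnc, the wound matrix protein tenascin C (log2 −6.33), and only Thbs1 was higher (camera adjusted p = 2.38e-12, adjusted p = 0.365 with an estimated correlation). All 13 basement membrane genes were lower, with Lama2, a laminin of muscle, at log2 −6.68 (camera adjusted p = 2.04e-08, adjusted p = 0.396 with an estimated correlation). Of 23 growth factors of fibrosis 18 were lower and 2 higher (camera adjusted p = 1.03e-05, adjusted p = 0.361 with an estimated correlation), and all 10 contractile genes were lower, with Cald1 at log2 −6.49 (camera adjusted p = 7.74e-09, adjusted p = 0.355 with an estimated correlation). In the other direction, 13 of 14 antigen presentation genes (camera adjusted p = 1.18e-09) and 11 of 15 lipid-handling genes (camera adjusted p = 5.79e-05) were higher, each with adjusted p = 0.355 with an estimated correlation. Of 17 pro-inflammatory genes 12 were higher, and 3 were lower, among them Saa3, an acute-phase protein, at 13.3 ± 2.41 against 335.0 ± 128.2 CPM (log2 −4.59, SE 0.19). That list was called at camera adjusted p = 1.3e-06 and had adjusted p = 0.355 with an estimated correlation. Of 16 senescence genes 11 were lower and 2 higher (camera adjusted p = 0.000579, adjusted p = 0.355 with an estimated correlation). Cdkn2a, a gene of cell cycle inhibitors whose products these counts do not separate, was at 0.751 ± 0.455 (0.497 without replicate 2) in immune-like and 30.2 ± 2.68 CPM in stromal-like cells (log2 −5.50, SE 0.22). Neural genes had 9 of 11 members lower (camera adjusted p = 0.00156, adjusted p = 0.355 with an estimated correlation). The 12 complement genes split into 3 higher, with the receptor C5ar1 at log2 7.94, and 9 lower, with the inhibitor Serping1 at log2 −6.25 (camera adjusted p = 0.0615, and 0.00016 without replicate 2). Of 12 dissociation stress genes 7 were lower and 1 higher, with Egr1 at 165.9 ± 17.2 against 1755 ± 266.7 CPM (camera adjusted p = 0.0715, and 0.0474 without replicate 2). For all 21 lists these counts were the same when adjusted over the list alone.

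Spp1, which encodes the matrix and cytokine protein osteopontin, was at 1389 ± 126.2 CPM in immune-like and 434.5 ± 166.0 CPM in stromal-like cells (log2 1.75, SE 0.26). Trem2, a lipid receptor of macrophages, was at 298.1 ± 49.2 against 1.63 ± 0.944 CPM (log2 7.66, SE 0.32), and Cd9, a tetraspanin, at 1397 ± 70.0 against 425.5 ± 16.2 CPM (log2 1.72, SE 0.08). With every class weighted equally, 1565 genes were higher and 2475 lower between immune-like and stromal-like cells, and the calls of Trem2 (log2 2.46), Cd9 (log2 0.12), Saa3 (log2 −2.91) and Cdkn2a (log2 −4.29) were lost. Il17ra, the receptor chain for IL-17A, was at 62.6 ± 10.2 and 72.5 ± 5.09 CPM (log2 −0.22, edgeR quasi-likelihood Benjamini-Hochberg adjusted p = 0.157), and its sign turned with classes weighted equally (log2 1.19). Collagen transcripts in immune-like droplets were also found in neutrophil-like cells, at a mean of 0.848, 1.10 and 0.791 Col1a1 UMIs per cell in replicates 1, 2 and 3.

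**Figure D2:**
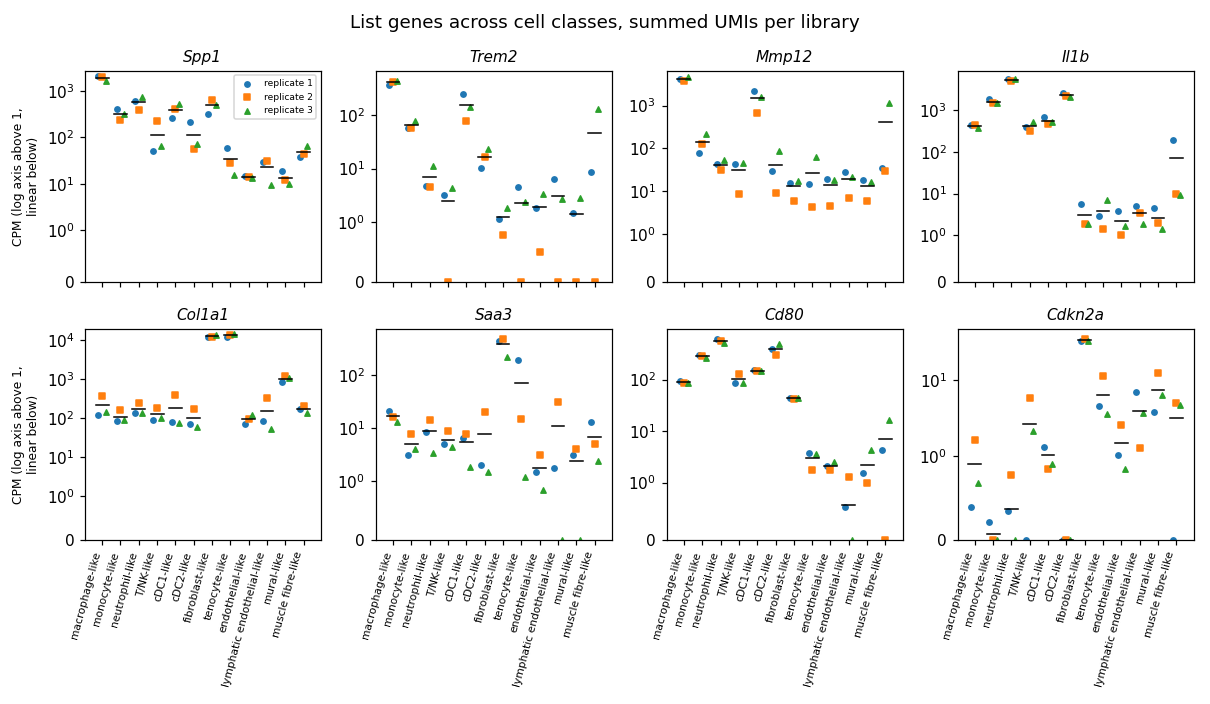
CPM of Spp1, Trem2, Mmp12, Il1b, Col1a1, Saa3, Cd80 and Cdkn2a in 12 cell classes, 1 marker per replicate and a line at the mean, on an axis that is logarithmic above 1 CPM and linear below. Neutrophil-like cells have the highest Il1b, at 5382 ± 418.8 CPM, and macrophage-like cells the highest Spp1, at 1869 ± 246.0 CPM.

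Macrophage-like cells were compared with the other immune-like cells. Most lipid-handling genes and 10 of 19 matrix proteases and inhibitors were higher, and most genes for cell division and inflammatory mediators were lower. These lists passed camera at the preset correlation, but no list did with an estimated correlation (smallest adjusted p = 0.329). Mmp12, the macrophage elastase, was at 4177 ± 480.2 CPM against 311.6 ± 108.4 CPM in the other immune-like cells (log2 3.80, SE 0.17). Lpl, lipoprotein lipase, was at 4249 ± 561.4 against 379.9 ± 176.5 CPM (log2 3.58, SE 0.18), Spp1 at 1867 ± 219.7 against 335.2 ± 70.2 CPM (log2 2.49, SE 0.13) and Trem2 at 406.0 ± 36.9 against 53.1 ± 14.2 CPM (log2 2.95, SE 0.17). Ccl4, a chemokine for lymphocytes and monocytes, was lower, at 57.7 ± 13.3 against 1001 ± 271.5 CPM (log2 −4.10, SE 0.24). The edgeR quasi-likelihood test gave Benjamini-Hochberg adjusted p = 2.65e-05 for Mmp12, 3.19e-05 for Lpl, 3.85e-05 for Spp1, 4.67e-05 for Trem2 and 4.89e-05 for Ccl4, each in the same direction in 3 of 3 libraries.

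Of 12906 genes, 1238 were higher and 2167 lower in macrophage-like cells, and of the 11668 that were neither markers nor used for clustering 1112 were higher and 1478 lower. Lipid-handling genes had 11 of 15 members higher and 0 lower (camera adjusted p = 2.52e-13, adjusted p = 0.329 with an estimated correlation), and matrix proteases and inhibitors 10 of 19 higher and 0 lower (camera adjusted p = 4.17e-10, adjusted p = 0.329 with an estimated correlation). Of 12 fusion genes 6 were higher, led by Atp6v0d2, a proton pump subunit of osteoclasts (log2 3.26, and 4.12 without replicate 1), and 2 were lower (camera adjusted p = 0.000278, adjusted p = 0.329 with an estimated correlation). Of 16 chemokines 8 were higher, with Cxcl14 at 106.8 ± 1.75 against 12.9 ± 2.46 CPM, and 4 were lower (camera adjusted p = 0.0148, adjusted p = 0.329 with an estimated correlation). Of 19 growth factors of fibrosis 6 were higher, with Pdgfa, a fibroblast mitogen, at log2 2.98, and 1 was lower (camera adjusted p = 0.0124, adjusted p = 0.329 with an estimated correlation). Of 15 cell cycle genes 14 were lower, with a median log2 of −4.02 (camera adjusted p = 4.97e-24, adjusted p = 0.329 with an estimated correlation). The other immune-like cells include 156 cDC1-like cells, 82 of them in cluster 29, whose cycling cells carry macrophage genes beside cDC1 genes, and without the clusters that mix 2 classes 10 of 14 were lower, with a median log2 of −1.40. Of 16 pro-inflammatory genes 13 were lower and 2 higher, with Cxcl3 the higher extreme at 994.1 ± 182.7 against 301.4 ± 143.1 CPM (camera adjusted p = 8.6e-08, adjusted p = 0.329 with an estimated correlation). Neutrophil-like cells, part of the other side, held the top level of 11 of the 14 pro-inflammatory genes ranked over 12 classes. Of 11 interferon response genes 6 were lower, with Isg15, a ubiquitin-like modifier, at 18.8 ± 0.391 against 92.8 ± 31.3 CPM (camera adjusted p = 0.0124, adjusted p = 0.562 with an estimated correlation). Of 14 antigen presentation genes 5 were lower (camera adjusted p = 0.000869, adjusted p = 0.329 with an estimated correlation). The IL-17 response list had 2 members higher and 5 lower of 9 (camera adjusted p = 0.0143, adjusted p = 0.329 with an estimated correlation). Type 2 macrophage genes went both ways, 3 higher and 6 lower of 14 (camera adjusted p = 0.0875), with the folate receptor Folr2 the higher extreme at log2 2.86. For all 21 lists the counts were the same when adjusted over the list alone.

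Fn1, fibronectin, was the leading matrix transcript of macrophage-like cells, at 6105 ± 337.8 against 1341 ± 231.0 CPM (log2 2.20, SE 0.09). Col1a1 was at 211.2 ± 137.8 (131.9 without replicate 2) and 136.6 ± 74.3 CPM (log2 0.57, not called), which turned to log2 −0.10 with no doublet removal, and Cd9 at 1527 ± 41.3 and 1037 ± 192.5 CPM (log2 0.58, not called). Genes outside the lists that were higher included Akr1b8, an aldo-keto reductase (log2 3.88), and Bhlhe41, a transcription factor (log2 3.86). Gpr171, a G protein-coupled receptor, was lower (log2 −4.88). With every class weighted equally the split became 1392 higher and 524 lower, and Cd80, the other ligand of T cell costimulation, at log2 −1.86 in the sums, lost its call (log2 −0.75). Il17ra, at 44.8 ± 1.79 against 95.8 ± 28.6 CPM (log2 −1.07), fell short of the threshold without replicate 1 (log2 −0.83).

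Subclusters of macrophage-like cells, made without the list genes, differed in which of these programs they carried. Of 8 subclusters, 6 had enough cells, and each was set against the mean of the logs of the others, while the levels given are the mean CPM of the others. Subcluster 1, 28.8% ± 3.21 of macrophage-like cells, had Mmp12 at 8288 ± 725.3 against 1931 ± 342.5 CPM (log2 2.59, SE 0.19, and 3.47 without subclusters 3 and 7) and Ocstamp, a fusion protein of osteoclasts, at 33.1 ± 12.2 against 6.00 ± 2.23 CPM (log2 3.11, and 3.99 without replicate 1 or 3.92 without subclusters 3 and 7), with Lpl, Gpnmb and Lgals3 also higher. Subcluster 2, 20.8% ± 4.0, had Ccl24, an eosinophil chemokine, at 790.5 ± 22.2 against 171.9 ± 101.3 CPM, the latter 114.0 CPM without replicate 1 (log2 2.86, SE 0.31, and 3.49 without subclusters 3 and 7), with Arg1, Pdcd1lg2 and Ccl22 higher among 13 type 2 genes and Folr2, Retnla and Il10 lower. In subcluster 4, 11.7% ± 0.927, the growth factor Pdgfc was at 86.9 ± 13.2 against 18.1 ± 5.25 CPM (log2 3.03, SE 0.17, and 3.83 without subclusters 3 and 7). Of the 13 type 2 genes, Stab1, Folr2, Retnla, Mgl2 and Il10 were higher there and Il1rn lower, and Spp1, Lpl and Cd9 were lower among the lipid genes. Subcluster 5, 8.39% ± 1.04, had 4 of 15 lipid-handling genes higher and 0 lower (Apoe, Fabp4, Fabp5 and Gpnmb), with the fatty acid binding protein Fabp5 at 1121 ± 203.9 against 391.8 ± 6.11 CPM. Subcluster 7, 4.97% ± 1.16, had 8 of 14 pro-inflammatory genes higher, with Ccl4 at 285.7 ± 62.9 against 29.4 ± 11.2 CPM (log2 3.55), and its leading genes included S100a8 and S100a9 of neutrophils. Its median doublet score was 0.058, against 0.026, 0.030, 0.026, 0.025 and 0.025 in subclusters 1 to 5. Of its 155 cells, 77, 38 and 26 came from clusters 15.1, 15.6 and 15.8, which are among the clusters that mix 2 classes. Its higher genes may therefore not be those of macrophages. Subcluster 3, 17.4% ± 4.70, had a median of 2417 UMIs per cell against 19853 in subcluster 1, and 22 of 25 matrix genes higher, with the collagen-binding protein Sparc at 1242 ± 937.0 against 70.2 ± 16.0 CPM (640.3, 2322 and 764.0 CPM in replicates 1, 2 and 3, and 702.1 CPM with log2 3.51 without replicate 2). The fibroblast genes Col1a1, Col1a2, Col3a1 and Dcn were among its leading genes. In all, edgeR's quasi-likelihood test made 183 calls of a list gene as higher and 163 as lower over the 6 subclusters. A gene counts once for each subcluster in which it was called. Subclusters 1, 2, 4 and 5 together had 66 higher and 157 lower calls. These became 99 and 97 without subclusters 3 and 7, so the excess of lower calls in these 4 depends on those 2. The 14 and 12 higher genes of subclusters 1 and 2 given next became 24 and 22, and the 66 lower of subcluster 2 became 30. In the order 1, 2, 3, 4, 5 and 7 there were 14, 12, 84, 25, 15 and 33 higher and 42, 66, 4, 31, 18 and 2 lower of 227, and adjusted over the list alone 14, 12, 88, 26, 15 and 33 higher and 44, 69, 4, 34, 20 and 2 lower. Leaving out replicate 3 moved the 12 of subcluster 2 to 7 and the 2 of subcluster 7 to 4, without replicate 1 the 4 lower genes of subcluster 3 became 2, and without replicate 2 they became 8 and the 2 of subcluster 7 became 1.

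T- and NK-like cells, which were few, were compared with the other immune-like cells. Most genes of lymphocyte effectors and of IL-17 producing cells were higher, and most for lipid handling and matrix proteases were lower. At the preset correlation camera called these lists, and it called none with an estimated correlation (smallest adjusted p = 0.236). Il23r, the receptor that sustains IL-17 producing lymphocytes, was at 71.1 ± 53.7 against 0.392 ± 0.162 CPM (log2 7.53, SE 0.50, and 40.1 CPM with log2 6.57 without replicate 1). Ifng, the cytokine interferon-γ, was at 37.9 ± 15.7 against 0.282 ± 0.256 CPM (log2 7.19, SE 0.61, and 7.85 without replicate 2, with 0.134 CPM in the other cells), and the proliferation gene Mki67 at 116.8 ± 28.8 against 26.8 ± 10.7 CPM (log2 2.17, SE 0.24). Most Mki67 UMIs lay in few cells, 100 in 7 cells of regulatory T-like cluster 18.7 and 62 in 5 cells of NK-like cluster 18.5. Clusters 18.6, 18.9 and 18.10 held 3, 2 and 4 UMIs. Mmp12 was lower, at 30.3 ± 19.5 against 3239 ± 682.6 CPM (log2 −6.74, SE 0.29). The edgeR quasi-likelihood test gave Benjamini-Hochberg adjusted p = 7.65e-07 for Il23r, 4.65e-06 for Ifng, 3.38e-05 for Mki67 and 5.25e-08 for Mmp12, each in the same direction in 3 of 3 libraries.

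Of 12513 genes, 1515 were higher and 1808 lower in T- and NK-like cells, and of the 11330 that were neither markers nor used for clustering 1192 were higher and 1546 lower. T cell effector genes had 15 of 16 members higher (camera adjusted p = 1.22e-22, adjusted p = 0.275 with an estimated correlation), and genes of IL-17 producing lymphocytes 5 of 6 (camera adjusted p = 1.85e-05, adjusted p = 0.275 with an estimated correlation). The cells were named by T, NK and innate lymphoid markers, so higher effector genes follow largely from that naming. Of 15 cell cycle genes 9 were higher, or 13 adjusted over the list alone, and 13 of 14 without the clusters that mix 2 classes (camera adjusted p = 5.16e-05, adjusted p = 0.428 with an estimated correlation). Lipid-handling genes had 14 of 15 members lower (camera adjusted p = 2.29e-17, adjusted p = 0.236 with an estimated correlation), and matrix proteases 14 of 19 (camera adjusted p = 6.46e-12, adjusted p = 0.275 with an estimated correlation). Of 12 fusion genes 9 were lower and 3 higher, among them Itgb3, an integrin chain (log2 4.20, camera adjusted p = 0.00165, adjusted p = 0.275 with an estimated correlation). Chemokines had 8 of 16 members lower, or 9 adjusted over the list alone, and 1 higher (camera adjusted p = 0.000359, adjusted p = 0.275 with an estimated correlation). Type 2 macrophage genes had 8 of 13 lower and 1 higher, or 2 adjusted over the list alone (camera adjusted p = 0.00917, adjusted p = 0.292 with an estimated correlation). For the other 18 lists the counts were the same when adjusted over the list alone. Outside the lists, Ctsw, a protease of cytotoxic lymphocytes, was at 94.3 ± 15.1 against 0.560 ± 0.459 CPM (log2 7.61, the latter level being 0.299 CPM without replicate 2), and Sh2d1a, a lymphocyte signaling adaptor, at log2 7.49. Dnm3, a dynamin, had 0 of the 1422724 UMIs of these cells and was at least 30.01-fold lower than in the other immune-like cells against a floor of 3 counts over the group. With classes weighted equally the split was 1362 higher and 698 lower, and the calls of Trem2 (log2 −6.94 in the sums, −2.89 so weighted) and Spp1 (log2 −4.08, and −1.01) were lost. The sums held 54, 39 and 41 cells in replicates 1, 2 and 3, and thinned to the smallest of the sums 820 genes were higher and 902 lower.

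Il17a itself was rare, with 48 UMIs in 12 of the kept cells. Of these, 34 UMIs lay in 5 of 134 T- and NK-like cells, all in the T-like cluster 18.6, where Il23r reached 337.1 CPM, and 11 UMIs lay in 5 of 677 unnamed cells. Unnamed cells also held 151 Il23r UMIs, in 25 cells, against 121 in 23 T- and NK-like cells. The share of T- and NK-like cells with an Il17a UMI was 3.70% in replicate 1 (exact binomial interval 0.452% to 12.7%), 7.69% in replicate 2 (1.62% to 20.9%), and 0 of 41 in replicate 3, which allows a share of up to 7.32% of cells with a UMI. Median depths there were 9722, 6335 and 8699 UMIs. Fibroblast-like cells, which should lack Il17a, had a UMI in 1 of 9769 cells at a median of 26439 UMIs, and macrophage-like cells in 0 of 3255, which allows up to 0.0922%. Il17ra was at 84.0 ± 3.73 CPM in fibroblast-like against 30.8 ± 3.08 CPM in the other stromal-like cells (log2 1.44, SE 0.08, edgeR quasi-likelihood Benjamini-Hochberg adjusted p = 1.56e-05). These other classes were unlike: blood endothelial-like cells held 110 Il17ra UMIs in 867 cells and tenocyte-like cells 104 in 302. Lymphatic endothelial-like cells held 359 in 235 and mural-like cells 330 in 319, at medians of 15094 and 14532 UMIs. The difference therefore holds against the pooled cells and not each class.

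Fibroblast-like cells were compared with the other stromal-like cells. Most genes for interstitial matrix and complement and 9 of 17 chemokines were higher, and most contractile genes were lower. The lists were called by camera at the preset correlation, while none was with an estimated correlation (smallest adjusted p = 0.639). Cxcl5, a neutrophil chemokine, was at 246.8 ± 56.8 against 4.34 ± 0.910 CPM (log2 5.83, SE 0.08). Col1a1 was at 13510 ± 1087 against 2730 ± 771.5 CPM (log2 2.34, SE 0.18), Spp1 at 518.2 ± 180.9 against 28.3 ± 7.63 CPM (log2 4.14, SE 0.29), and C4b, a complement component, at 517.3 ± 33.0 against 28.3 ± 4.79 CPM (log2 4.21, SE 0.14). Tagln, an actin-binding protein of smooth muscle, was lower, at 21.3 ± 3.45 against 523.0 ± 135.1 CPM (log2 −4.60, SE 0.23). The edgeR quasi-likelihood test gave Benjamini-Hochberg adjusted p = 1.03e-07 for Cxcl5, 6.2e-05 for Col1a1, 4.3e-05 for Spp1, 1.87e-06 for C4b and 1.14e-05 for Tagln, each in the same direction in 3 of 3 libraries.

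Of 16741 genes, 2125 were higher and 2764 lower in fibroblast-like cells, and of the 15039 that were neither markers nor used for clustering 1927 were higher and 1764 lower. Interstitial matrix genes had 21 of 25 members higher and 1 lower, with the proteoglycan Vcan at log2 3.43 (camera adjusted p = 9.01e-12, adjusted p = 0.639 with an estimated correlation). Complement genes had 8 of 12 higher and 0 lower (camera adjusted p = 3.62e-09, adjusted p = 0.639 with an estimated correlation), and chemokines 9 of 17 higher and 1 lower (camera adjusted p = 1.32e-05, adjusted p = 0.639 with an estimated correlation). Of 20 matrix proteases and inhibitors 11 were higher, with the inhibitor Timp1 at 1161 ± 184.8 against 78.5 ± 27.9 CPM, and 3 were lower (camera adjusted p = 0.000146, adjusted p = 0.639 with an estimated correlation). Of 24 growth factors of fibrosis 13 were higher, with Wnt2 at log2 4.42, and 3 were lower, or 4 adjusted over the list alone (camera adjusted p = 0.013, adjusted p = 0.695 with an estimated correlation). Of 16 senescence genes 7 were higher and 2 lower (camera adjusted p = 0.0388, adjusted p = 0.738 with an estimated correlation). Cdkn2a was at 36.1 ± 1.72 against 3.84 ± 1.67 CPM (log2 3.22, SE 0.18), while Cdkn1a, the inhibitor p21, was at 202.0 ± 29 and 155.9 ± 24.3 CPM (log2 0.38, not called). Contractile genes had 7 of 10 members lower and 1 higher, Lrrc15, a marker of activated fibroblasts (log2 2.69, and 3.35 without replicate 2, camera adjusted p = 0.00577, adjusted p = 0.639 with an estimated correlation). Hypoxia and angiogenesis genes had 7 of 15 lower and 3 higher (camera adjusted p = 0.00852, adjusted p = 0.695 with an estimated correlation). Cell cycle genes had 11 of 15 higher but the list did not pass camera (adjusted p = 0.0915, and 0.00379 without replicate 2), and in the basement membrane, lipid-handling, pro-inflammatory, neural and stress lists, none of which was called, the median, mean and test differed in sign. Neural genes had 4 of 11 higher, or 5 adjusted over the list alone, and for the other 19 lists the counts were the same. Cd80 was at 46.5 ± 0.933 against 2.24 ± 0.860 CPM (log2 4.46, SE 0.17, edgeR quasi-likelihood Benjamini-Hochberg adjusted p = 3.15e-06). Among genes outside the lists, Adgrd1, an adhesion receptor, was at log2 5.15 and Scara5, a scavenger receptor for ferritin, at log2 4.89. With classes weighted equally the split was 2309 higher and 463 lower, and Saa3, at 403.6 ± 150.5 against 17.2 ± 20.1 CPM (log2 4.88), was at log2 6.09 without replicate 1, with 6.02 CPM in the other cells.

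Subclusters of fibroblast-like cells differed in the list genes they carried. Of 14 subclusters 13 were tested, numbered by size. Subclusters 1 and 6, 21.1% and 7.61% of fibroblast-like cells, shared the stromal protease Mmp3 and Saa3 among their named genes, with Saa3 at 959.5 ± 262.9 and 1637 ± 819.7 CPM against 260.3 ± 110.6 and 203.8 ± 97.5 CPM in the others (log2 3.46, SE 0.32, and 4.23, SE 0.31). Subcluster 3, 11.1%, had Spp1 at 1984 ± 602.5 against 158.4 ± 66.2 CPM (log2 5.65, SE 0.16), with 7 of 9 contractile genes, Acta2 among them, and 9 of 15 cell cycle genes higher and 7 of 11 complement genes lower. Subcluster 4, 10.9%, had Lrrc15 at 177.3 ± 7.60 against 54.1 ± 2.84 CPM (log2 3.21, SE 0.13), Cd80 at 92.3 ± 6.20 against 27.9 ± 2.74 CPM and Tnc at 802.6 ± 94.95 against 461.6 ± 40.9 CPM. Subcluster 5, 9.24%, had Bmp4, a bone morphogenetic protein, at 63.1 ± 4.07 against 5.55 ± 2.77 CPM (log2 5.08, SE 0.29), and the chemokine Cxcl14 at 1171 ± 296.6 against 361.4 ± 64.8 CPM. In subcluster 7, 6.09%, 10 of 11 interferon response genes were higher, with the interferon-induced chemokine Cxcl10 at 483.0 ± 81.7 against 44.7 ± 15.8 CPM (log2 4.12, SE 0.25). Subcluster 8 had Eln, elastin, at 3807 ± 933.7 against 317.0 ± 29.95 CPM. Subcluster 9, 3.05%, had all 15 cell cycle genes higher, with Mki67 at 399.1 ± 17.8 against 1.29 ± 0.143 CPM, and 9 of 11 complement genes lower. Subcluster 10, 3.22%, had Tgm2, a protein-crosslinking transglutaminase, at 598.7 ± 60.4 against 77.5 ± 2.21 CPM (log2 3.77, SE 0.08), with 8 of 11 complement and 8 of 11 interferon genes lower. Subclusters 2 and 12 had the cytokine Il18 among their named genes, at 75.1 ± 6.42 and 57.1 ± 8.90 CPM, and subcluster 13 the lipid carrier Apoe, at 1185 ± 372.5 against 99.5 ± 22.6 CPM. Subcluster 11 had 10 of 12 dissociation stress genes lower and Il34, a growth factor of macrophages, higher at 77.3 ± 2.03 against 44.0 ± 2.89 CPM. In all, edgeR's quasi-likelihood test made 565 calls of a list gene as higher and 477 as lower over the 13 subclusters. A gene counts once for each subcluster in which it was called. A single subcluster had 27 to 60 higher and 10 to 61 lower of 254, and adjusted over the list alone 27 to 60 higher and 10 to 62 lower.

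**Figure D3:**
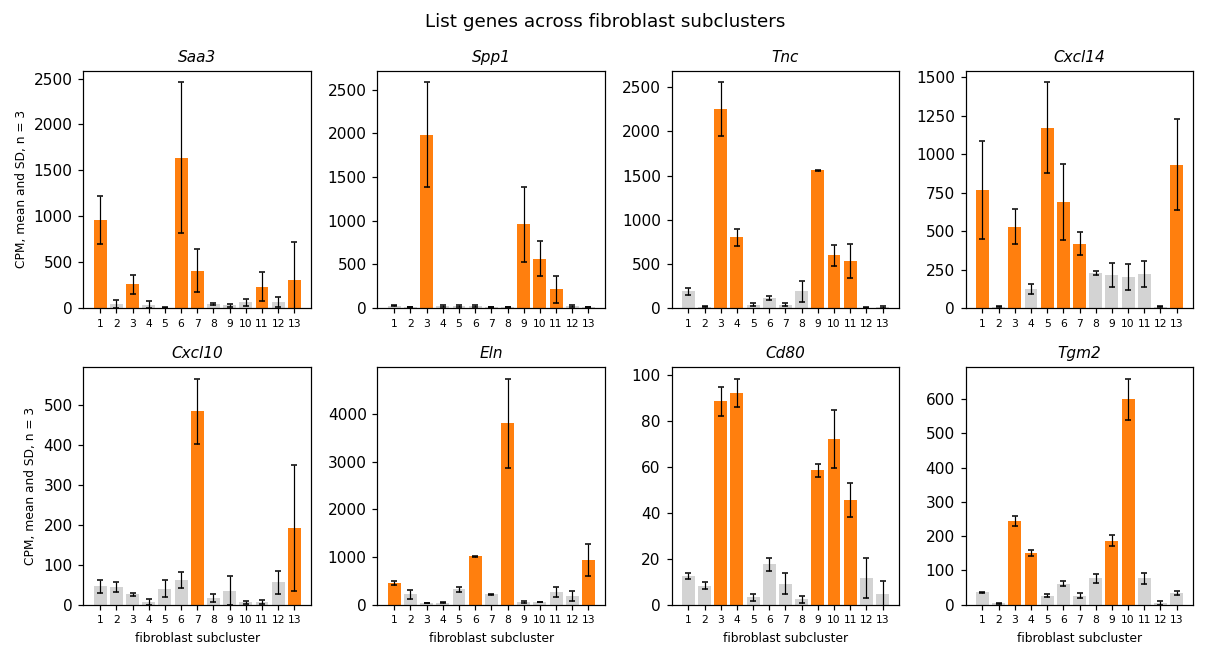
CPM of Saa3, Spp1, Tnc, Cxcl14, Cxcl10, Eln, Cd80 and Tgm2 in the 13 tested fibroblast-like subclusters, bars giving the mean and error bars the SD (n = 3), with orange bars for genes called higher than the mean of the other subclusters and grey for the rest. Spp1 is highest in subcluster 3, at 1984 ± 602.5 CPM, and Tgm2 in subcluster 10, at 598.7 ± 60.4 CPM.

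Endothelial-like cells, lymphatic ones included, were compared with the other stromal-like cells. Fibroblast-like cells gave 77230826 of the 82109957, 142198168 of the 147639981 and 65335823 of the 68326505 UMIs of that other side in replicates 1, 2 and 3. The comparison is thus largely against fibroblast-like cells. Most interstitial matrix, complement and chemokine genes were lower, in lists that camera called at the preset correlation, while no list was called with an estimated correlation (smallest adjusted p = 0.291). Fabp4, a fatty acid binding protein of capillaries, was at 2757 ± 843.3 against 14.4 ± 10.0 CPM (log2 7.74, SE 0.29, the latter level being 8.56 CPM without replicate 3), Dll4, a Notch ligand of sprouting vessels, at 86.3 ± 16.4 against 0.130 ± 0.0300 CPM (log2 9.47, SE 0.17), and Stab1, a scavenger receptor, at 370.4 ± 42.0 against 7.46 ± 0.749 CPM (log2 5.63, SE 0.13), all higher. Among the 12 classes with at least 20 cells in each library, Dll4 and Stab1 were highest in lymphatic endothelial-like cells. Fabp4 was highest in blood endothelial-like cells. Col1a1 was lower, at 111.4 ± 54.5 against 13160 ± 1041 CPM (log2 −6.98, SE 0.32), as was C3, the central complement component, at 57.3 ± 24.0 against 3033 ± 279.6 CPM (log2 −5.78, SE 0.24). The edgeR quasi-likelihood test gave Benjamini-Hochberg adjusted p = 3.93e-07 for Fabp4, 2.03e-08 for Dll4, 3.88e-08 for Stab1, 1.04e-06 for Col1a1 and 6.73e-07 for C3, each in the same direction in 3 of 3 libraries.

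Of 16554 genes, 2349 were higher and 3335 lower in endothelial-like cells, and of the 14918 that were neither markers nor used for clustering 1772 were higher and 2847 lower. Interstitial matrix genes had 23 of 25 members lower and 0 higher (camera adjusted p = 2.94e-39, adjusted p = 0.291 with an estimated correlation). Complement had 9 of 12 lower and 0 higher (camera adjusted p = 1.65e-10, adjusted p = 0.291 with an estimated correlation), and chemokines 11 of 17 lower and 0 higher, with Cxcl14 at 3.06 ± 0.998 against 455.1 ± 110 CPM (camera adjusted p = 2.35e-10, adjusted p = 0.37 with an estimated correlation). Proteases and inhibitors had 13 of 20 lower and 2 higher, among them the inhibitor Timp3 at log2 1.47 (camera adjusted p = 9.21e-07, adjusted p = 0.291 with an estimated correlation). Of 23 growth factors of fibrosis 15 were lower and 4 higher, with Pdgfb, which recruits mural cells, at 132.6 ± 15.2 against 0.747 ± 0.271 CPM (log2 7.55, camera adjusted p = 2.19e-05, adjusted p = 0.37 with an estimated correlation). Of 16 senescence genes 9 were lower and 2 higher, with Igfbp7, a secreted binding protein of vessels, at 2515 ± 82.3 against 828.3 ± 32.5 CPM (camera adjusted p = 0.00139, adjusted p = 0.33 with an estimated correlation). Of 10 contractile genes 5 were lower and 1 higher (camera adjusted p = 0.0407, adjusted p = 0.37 with an estimated correlation). The basement membrane list, with 4 higher, among them the laminin Lama5 at log2 4.84, and 2 lower of 13, and the hypoxia list, with 8 higher and 3 lower of 15 (camera adjusted p = 0.081), were not called. Among the 12 ranked classes Lama5 was highest in mural-like cells, which are on the other side here. The hypoxia list had camera adjusted p = 0.0167, 0.0241 and 0.00184 without replicates 1, 2 and 3. The lists of type 2 macrophage, IL-17 producing lymphocyte and interferon genes, not called either, had a median, mean and test of different sign. Cell cycle genes had 6 of 15 lower, or 7 adjusted over the list alone, and for the other 20 lists the counts were the same. Among genes outside the lists Gpr182, a chemokine scavenger of vessels, was at log2 9.03 and Celsr1, an adhesion protein of lymphatic valves, at log2 8.78, and the homeobox gene En1 was lower (log2 −8.61). With classes weighted equally the split was 1743 higher and 1093 lower, and the calls of Il17ra (log2 −1.62 in the sums, −0.43 so weighted), Cd80 (log2 −4.84, and −0.98) and Cdkn2a (log2 −4.08, and −0.28) were lost.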

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

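Of the tests here, that of macrophage RNA in fibroblast-like droplets and that of Cd80 UMIs in doubted clusters were chosen only after the level of Cd80 had been seen. Clusters left without a name entered no comparison. Of the 10 with ordinary depth, each looked at in its leading gene alone, 4 had that gene above its level in every named class and above the limit that a count of 0 allows. Cluster 18.11, with 12 cells of which 10 came from replicate 2, had the antibody light chain gene Igkc at 118800 CPM (31602 UMIs), against 1065 CPM in the highest named class, cDC1-like cells, and it scored highest for B cell and next for plasma cell markers. Cluster 14.8, with 24 cells of which 21 came from replicate 2, had Brinp3 at 1241 CPM against 397.6 CPM in fibroblast-like cells. Cluster 18.3, with 47 cells scoring for both T cell and macrophage markers, had Tnfrsf4, a costimulatory receptor of activated T cells, at 175.5 CPM against 157.4 CPM in T- and NK-like cells, an excess inside the spread of that class over the libraries (170.4 ± 81.2 CPM). Cluster 20.5, with 33 cells scoring for dendritic cell and macrophage markers, had Retnla, a type 2 macrophage gene, at 3234 CPM against 1191 CPM in Schwann-like cells, where it was at 4865 CPM in replicate 3 and 0 in the others. No test set these levels against each other.

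Collagen and other fibroblast transcripts were high in macrophage-like subcluster 3, which is shallow. Free RNA present in every droplet alike predicted a ratio of Col1a1 UMIs per droplet between subclusters 3 and 1 under 2, and the lowest ratio of the 3 libraries was 1.515 and the highest 7.642, in replicate 2, so this explanation cannot be told apart from others. Medians per droplet were 2, 3 and 1 UMIs in subcluster 3 and 2 in each library in subcluster 1. Mean Col1a1 UMIs per droplet in replicates 1, 2 and 3 were 3.25, 20.9 and 2.93 in subcluster 3. They were 0.65, 0.75 and 0.688 in the shallow subcluster 6, with 12 cells in replicate 2, and 0.848, 1.10 and 0.791 in neutrophil-like cells. These lower values go against free RNA in every droplet alike, while the lowest ratio to subcluster 1 goes with it. The ratios of Col1a2 and Col3a1 to Col1a1 in subcluster 3 were 0.797 to 0.966 times those in fibroblast-like cells of the same library, which is consistent with fibroblast RNA, whether free, in fragments or in doublets, as the source. With the design giving no second group, no biological explanation was tested.

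Immune-like cells took a smaller share of replicate 2 than of the other libraries. Before any filter or cluster name, 44.4%, 19.6% and 37.7% of the barcodes of replicates 1, 2 and 3 had a Ptprc UMI, against 7.42%, 2.75% and 5.99% of fibroblast-like cells, at median depths of 32005, 24375 and 28235.5 UMIs. The share in replicate 2 was 0.519 times the lower of the others, which argues against the filters, doublet removal or names as the source of the difference. The magnetic separation and remix were not recorded per library, so a different mix stays open, and no biological explanation was tested.

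Cd80, best known from antigen-presenting cells, was called higher in fibroblast-like than in other stromal-like cells. Its level in fibroblast-like cells was 0.479 to 0.515 times that in macrophage-like cells, and this ratio was at least 104.18 and at most 409.16 times that of the macrophage genes Ptprc, Cd86, Ctss, Lyz2 and Cd74, which argues against macrophage RNA or doublets. A few doubted clusters predicted under 20 CPM outside the highest subcluster, yet 5 of the 13 tested subclusters (3, 4, 9, 10 and 11) had at least 20 CPM in every library, short of the majority set beforehand as evidence against. Those 5 hold 3010 of the 9769 cells. Clusters doubted for low UMIs or mixed markers hold 0 of these 3010 and 3 of the 12267 Cd80 UMIs of fibroblast-like cells. They hold only 87 fibroblast-like cells, with a median of 974 UMIs, so a small share was set in advance by their size. The Cd80 UMIs thus lie outside these clusters, and the share decides nothing further. No biological explanation was tested.

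With 3 sums on each side there are 10 splits, too few for a share under 0.05. The counts of called genes were 8691 for immune-like against stromal-like cells, 3405 for macrophage-like, 3323 for T- and NK-like, 4889 for fibroblast-like and 5684 for endothelial-like cells, 1 of the 10 splits reached each count, and the highest of the other splits was 0 genes each time by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. At an unadjusted p under 0.05 the highest other splits had 34, 59, 169, 121 and 128 genes in the same order. The real split parts both sums of all 3 libraries. The 3 other splits that do so had at most 1, 15, 48, 23 and 13 genes at that unadjusted threshold, and the remaining 6 part the sums of only 1 library. Only edgeR was run on the splits. For subclusters, labels were shuffled within each library. Of 40 draws for macrophage-like subclusters only the real one reached its 346 list gene calls, with 74 the highest of the others, and of 21 draws for fibroblast-like subclusters only the real one reached 1042, with 45 the highest. The classes and the subclusters were both made from the expression of the same cells. The real grouping was therefore bound to lead, and neither the splits nor these shuffles test chance. The p-values between classes share this limit.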

How the results depend on the processing

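Among the settings here, those that leave out clusters of very low UMIs, clusters that mix 2 classes, or macrophage-like subclusters 3 and 7 were chosen only after seeing the data. Of 166 gene counts recomputed under an alternative, 157 stayed within 1.5 times, as did 28 of 30 subcluster totals and 261 of 274 counts of single subclusters. Of 3786 values of named genes 3634 kept their direction and side of the threshold, 114 were no longer past it, 11 newly were and 27 reversed, and all 411 values of named subcluster genes kept both. Few UMIs limit the T- and NK-like comparison. Without clusters that mix 2 classes, the cell cycle genes lower in immune-like than in stromal-like cells became 11 of 15 in place of 2. With no replicate block the counts were 3481 higher and 5215 lower for immune-like, 1210 and 2164 for macrophage-like, 1694 and 1947 for T- and NK-like, 2116 and 2743 for fibroblast-like and 2381 and 3352 for endothelial-like cells, and 180 and 146 for macrophage-like and 551 and 465 for fibroblast-like subclusters.

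With classes weighted equally the immune-like against stromal-like comparison gave 1565 genes higher and 2475 lower, and genes lower were 524 for macrophage-like, 698 for T- and NK-like, 463 for fibroblast-like and 1093 for endothelial-like cells. This weighting moved the median log2 difference of all genes from −0.104 to −0.218, from 0.039 to 0.182, from −0.112 to 0.078, from −0.007 to 0.191 and from −0.055 to 0.105, in that order, and the share of called genes that were higher from 40.1% to 38.7%, from 36.4% to 72.7%, from 45.6% to 66.1%, from 43.5% to 83.3% and from 41.3% to 61.5%. By construction it fits fewer genes, 13459 in place of 17630 for the first comparison, and lets rare classes count as much as common ones; the cause of the rest was not tested. Under it these genes reversed in the immune-like against stromal-like comparison: Pdgfb (log2 −0.39), Hspa1a (−1.11) and Il17ra (1.19). Macrophage-like reversals were Cdkn1a 0.22, Mmp9 1.15, Thbs1 0.10, Ccl22 0.52, Gzmb 1.33 and Lcn2 0.44; T- and NK-like, C3ar1 0.011; fibroblast-like, Ccn2 0.26, Igfbp7 1.53 and Csf3 3.80; endothelial-like, Tagln −1.21, Trem2 −0.014 and Ube2c 3.78.

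Thinning the sums, which leaves 5514 of 12513 genes testable for T- and NK-like cells, gave 820 genes higher and 902 lower there, and 2103 lower for endothelial-like cells. With no doublet removal, macrophage-like Pdgfra became −0.15, Col1a1 −0.10 and endothelial-like Ptprc 0.50. Ptprc in endothelial-like cells was also 0.015 with at least 1000 genes per cell, 0.084 with fixed list genes allowed in clustering and 0.17 without clusters of very low UMIs. Leaving out 1 replicate, the ranges of genes that reversed were −0.21 to 0.025 for Il17ra and −1.04 to 0.07 for Pdgfra in T- and NK-like cells (above 0 without replicate 2), and in endothelial-like cells −0.38 to 0.45 for Trem2 (below 0 without replicate 1) and −0.58 to 0.16 for Ptprc (above 0 without replicates 1 or 3), none past the threshold. Genes lower in single fibroblast-like subclusters fell to 4 from 10 in subcluster 1 and to 12 from 22 in subcluster 7 without replicate 2, and to 5 from 11 in subcluster 6 without replicate 2 or 3. Without subclusters 3 and 7, the other 4 macrophage-like subclusters gave 99 calls of list genes as higher and 97 as lower, against 66 and 157 before. The higher genes rose to 24 from 14 in subcluster 1 and to 22 from 12 in subcluster 2, and the lower ones fell to 30 from 66 in subcluster 2.

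Lists called by camera fell to 0 in each comparison with an estimated correlation, from 13, 12, 13, 8 and 7 (smallest adjusted p = 0.355, 0.329, 0.236, 0.639 and 0.291, with 2, 1, 1, 1 and 3 lists at an unadjusted p under 0.05), while fry, which tests each list by itself, called 19, 14, 9, 12 and 14 at the same threshold. With 2 residual degrees of freedom in each comparison, the calls lost with an estimated correlation do not show that these lists are unchanged. Leaving out a replicate kept the camera counts at the preset correlation within 1.5 times. The pro-inflammatory list of T- and NK-like cells lost its call without replicate 2 (adjusted p = 0.143, and 0.00917 with all). Newly called, besides lists named in the report, were interstitial matrix (0.0172 without replicate 1) and IL-17 producing lymphocyte genes (0.0175 without replicate 2) in macrophage-like cells, stress (0.022 without replicate 1, 0.0111 without replicate 3) and senescence genes (0.0169 without replicate 3) in T- and NK-like cells, and pro-inflammatory genes in endothelial-like cells (0.0218 without replicate 2). Of 241 shares 225 moved by under 1 SD. Those that moved were cDC1-like 0.277% and cDC2-like 0.530% without clusters that mix 2 classes, endothelial-like 3.64% at Leiden resolution 2.0 and with list genes in clustering and 3.37% without low-UMI clusters, cDC2-like 1.06% and muscle fibre-like 0.517% with at least 1000 genes per cell, cDC2-like 0.488%, migratory DC-like 0.143% and unnamed 5.09% with list genes in clustering, migratory DC-like 0.132% and unnamed 9.58% at a mitochondrial share under 10%, mast-like 0.224%, Schwann-like 0.319% and unnamed 6.28% with no doublet removal, and unnamed 6.56% at resolution 2.0. The muscle fibre-like class has 0 cells, and so no value, without low-UMI clusters. The causes of these moves of counts and shares were not tested; the cause was not tested for the lists either.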

Other observations

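None of the values here comes from a test chosen after the result was seen, and the levels are given without a test. Among the 12 classes with enough cells in each library, neutrophil-like cells held the top level of 11 of the 14 pro-inflammatory genes that had the same top class in all 3 libraries with at least 20 CPM. The neutrophil chemokine Cxcl2 was at 17340 ± 243.6 CPM there against 1923 ± 270.3 CPM in macrophage-like cells, the next class (SD, n = 3). Il1b was at 5382 ± 418.8 CPM against 2267 ± 273.7 in cDC2-like cells, the inflammasome gene Nlrp3 at 1372 ± 100.8 against 314.8 ± 65.5, and Tnf at 658.4 ± 61.5 CPM. Cd80 was also highest in neutrophil-like cells, at 559.2 ± 51.2 CPM, followed by 390.4 ± 91.4 CPM in cDC2-like cells. These levels are shares of the UMIs of a class. Median depth was 5137 UMIs in neutrophil-like and 15562 in cDC2-like cells, so the order in UMIs per cell can differ. Of 13 lipid-handling genes ranked in the same way, 10 had their top level in macrophage-like cells.

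The genes that follow were ranked over the same 12 classes. Mural-like cells held the top level of Il6, at 1144 ± 418.4 CPM against 199.8 ± 47.2 CPM in fibroblast-like cells, and of Steap4, a metalloreductase induced by IL-17 and TNF, at 709.7 ± 160.9 against 172.6 ± 19.2 CPM. Basophil-like cells, too few to be ranked, had Il6 among the leading genes of their cluster 31.2, with 27 cells. Lymphatic endothelial-like cells led in Stab1, at 1007 ± 44.0 against 109.1 ± 11.1 CPM in blood endothelial-like cells, and in Tnfrsf11a, the receptor for the osteoclast factor RANKL, at 94.8 ± 17.6 CPM. The proliferation genes Top2a and Mki67 were highest in cDC1-like cells, at 388.0 ± 34.4 and 331.0 ± 72.8 CPM, ahead of T- and NK-like cells at 126.4 ± 7.27 and 125.8 ± 32.6 CPM. That class includes cluster 29, cycling cells with macrophage genes beside cDC1 genes. Igf1, a growth factor of muscle, was highest in tenocyte-like cells, at 1554 ± 199.0 CPM against 591.5 ± 19.4 CPM in fibroblast-like cells.

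The T- and NK-like class held clusters of several kinds, pooled over the libraries and so without an error. In the 39 NK-like cells of cluster 18.5 there were 45 Ifng UMIs in 17 cells and 180 Gzmb UMIs in 23 cells. The 27 regulatory T-like cells of cluster 18.7 held 120 Foxp3 UMIs in 19 cells. The 20 cells of cluster 18.9, scoring for type 2 innate lymphoid markers, held 241 UMIs of Areg, an epidermal growth factor family ligand, in 17 cells (1255 CPM) and 14 Il5 UMIs in 7 cells (72.9 CPM). Cluster 18.7 also held 102 Areg UMIs, in 16 cells, and 28 Il5 UMIs, all in 1 cell (96.6 CPM). The labels give no sex for the mice. Xist, the transcript of the inactive X chromosome, had 71957, 105570 and 58191 UMIs in replicates 1, 2 and 3, and the Y-linked gene Ddx3y 8, 14 and 4.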
